A study of Danio rerio with 9 samples.

How the data were processed

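Polyadenylated RNA was sequenced from 9 pools of 30 zebrafish embryos at 30 hours post fertilisation, 3 pools for each of 3 genotypes of npc2. Groups were taken from the genotype label and replicate numbers from the sample titles. Per the submitters' processing notes, the reads were processed with cutadapt 1.18, HISAT2 2.1.0 and featureCounts 1.6.3 and the genome build was GRCz11 (danRer11). The annotation release, the strand setting and the counting options are not given in the sources used here. The values deposited by the authors are whole-number counts per gene, not normalized. Between 96.3% and 97.5% of the counts from 1 to 19 in a library were even, so the deposited counts may hold 2 counts for most fragments. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and near-identical copies, such as the her4, her15, globin, crystallin and gvin genes, are uncertain one by one.

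Total counts were 65070813, 59854684 and 55144480 in heterozygous replicates 1 to 3, 69360234, 62594019 and 42535508 in homozygous replicates 1 to 3, and 38564405, 64100420 and 55492163 in wild-type replicates 1 to 3. The 10 most abundant genes held 8.89% to 9.71% of a library's counts. Scaling factors by the trimmed mean of M values (TMM) were 0.981 to 1.02. Libraries of a genotype differed by more than sampling noise (chi-square per degree of freedom of 2.53 to 7.00, computed on counts divided by 2), so no library was treated as a duplicate.

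Of 32520 gene IDs counted, 29201 had a symbol in the names table given with the data. A total of 1719 symbols were carried by 2 or more IDs, together 6136 IDs, because fish paralogues share a symbol there, and the full ID is given for such genes. Symbols are printed as that table gives them.

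The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit) on the counts as deposited, with all 9 libraries in 1 fit, no block for the replicate number, edgeR's default filter by expression, TMM scaling and Benjamini-Hochberg adjustment within each comparison. The filter kept 20375 genes and dropped 12145. A gene was called at an adjusted p under 0.05, with no limit on the fold change. Adjusted p-values of single genes are from this test, and values after ± are standard errors for log2 fold changes and standard deviations over 3 pools for CPM. The standard errors are approximate: each is the absolute log2 fold change divided by the square root of the F statistic. CPM values were scaled by TMM.

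Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. Camera compares a list with all other genes, here with an inter-gene correlation preset to 0.01 and, as an alternative, estimated per list. The 33 lists held 1166 entries, of which 828 matched by symbol, 26 by alias and 272 after removing a paralogue suffix, while 40 had no match. Adjustment was over the 33 lists of a comparison. These lists, the tests of the comparisons, the alternatives except the halved counts, and the wording of the rule for named genes were fixed before the data were examined.

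The rule named NPC2 and NPC1 and, per comparison, the 10 largest rises and 10 largest falls. These were taken among called genes with a mean of at least 5 CPM, a symbol that is not a clone or locus name, and the 3 libraries of one genotype all above the 3 of the other. The rule as written left out every symbol starting with BX, CR, CU, CT, FP, FO, AL or CABZ. It was applied only where 5 or more digits follow, as in clone names, since it would otherwise leave out gene symbols such as CTSB, CTCF and CRY1. This reading was chosen after the data were seen. The rule also named up to 4 members by lowest adjusted p of each called list in the direction of the list, and of the Notch component, Notch target, cholesterol synthesis, lysosome, otic vesicle and erythroid lists whether called or not. Only part of the genes so named are described. A withheld item is not reported here.

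The procedure was tested on simulated counts with the real means and library sizes and 200 of 20375 genes changed, in 5 simulations per comparison. For homozygous against wild type, 47.2%, 70.4% and 93.0% of genes changed 1.5-fold, 2-fold and 4-fold were called, with 8.96% of calls false. For heterozygous against wild type these were 56.4%, 74.0%, 88.5% and 6.06%, and for homozygous against heterozygous 56.7%, 70.1%, 90.6% and 7.65%. The share of false calls was above the nominal 5% in each. Far fewer genes were changed here than were called in the real comparisons, so the share may differ there. The cholesterol synthesis list, changed 1.5-fold, was called in 5 of 5 simulations per comparison, with 0 other lists called. Genes were simulated independently of each other, so this does not test false list calls where the genes of a list move together.

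The alternatives were DESeq2 1.42.0, limma-voom, edgeR's RLE and upper-quartile scaling, no low-count filter, a filter of 1 CPM in 3 libraries, a fit of only the 2 genotypes compared, the replicate number as a block, leaving out each library, and for lists an estimated correlation, camera on ranks and fry. Counts halved and rounded up were added after seeing the data. Chromosomes came from a RefSeq gene table of assembly GRCz12tu, another build than that of the counts, and no coordinates are given. Tables were read with pandas 2.3.3 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.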

Results

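Polyadenylated RNA was sequenced from zebrafish (Danio rerio) embryos at 30 hours post fertilisation. The embryos carried 0, 1 or 2 mutant copies of npc2, which encodes a soluble lysosomal protein that binds cholesterol. Each genotype was represented by 3 pools of 30 embryos. Homozygous embryos (maternal-zygotic mutants) and heterozygous embryos (maternal mutants) were siblings from the same crosses and were sorted by phenotype. Wild-type embryos came from other crosses, between wild-type siblings of the mutants' parents, so that mother, parents and clutch differed together with genotype in both comparisons with wild type. According to the series design, homozygous and heterozygous mutants were compared with wild type. The labels describe the pools of a genotype as separate but do not name their clutches or days, so p-values measure the spread between these pools. The total count per library ranged from 38564405 in wild-type replicate 1 to 69360234 in homozygous replicate 1. At these depths, 3 counts equalled 0.0433 to 0.0778 CPM (counts scaled to a common library total), a limit that covers counting error only. If most fragments hold 2 counts, 3 counts stand for fewer than 3 fragments and this limit is too low. A total of 20375 genes entered the tests.

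Libraries grouped by genotype. The first principal component of log2 CPM held 42.4% of the variance and separated homozygous libraries (scores of 51.0 to 55.6) from wild-type libraries (-49.5 to -37.0), with heterozygous libraries between them (-12.0 to -8.21). The second component held 19.7% and set heterozygous libraries (34.8 to 41.5) apart from both other genotypes. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.986 to 0.990 within genotypes. Between genotypes they were 0.974 to 0.980 for wild type and heterozygous, 0.972 to 0.975 for heterozygous and homozygous, and 0.962 to 0.970 for wild type and homozygous.

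**Figure D1:**
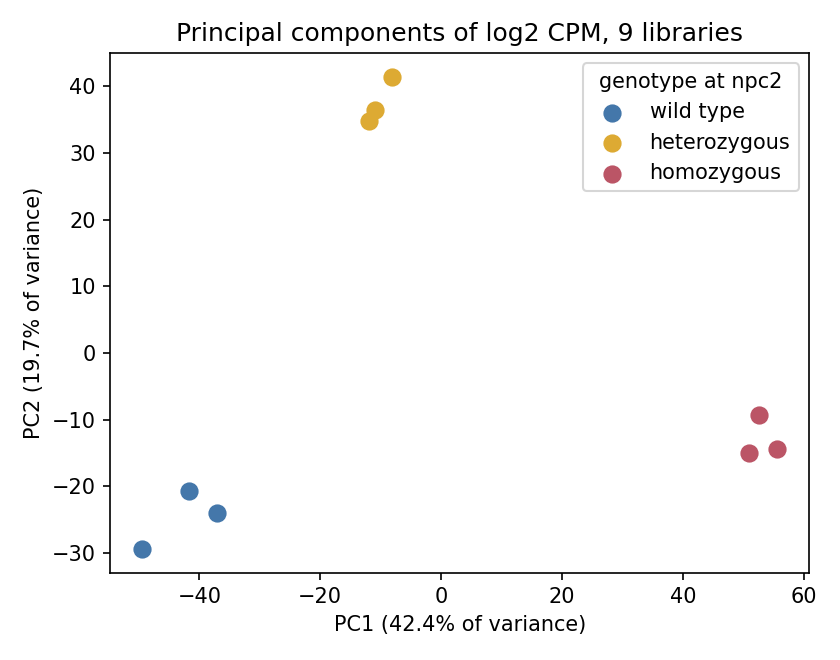
Scores of the 9 libraries on the first component (x axis, 42.4% of variance) and the second component (y axis, 19.7% of variance) of log2 CPM, coloured by genotype. The 3 libraries of each genotype lie together, with heterozygous libraries between the others on the x axis.

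The mutated gene was measured in every library first. NPC2 (ENSDARG00000090912) was at 266 ± 11.5 CPM in wild type (SD, n = 3), 144 ± 2.37 in heterozygous and 37.0 ± 6.35 in homozygous embryos. Single libraries held 255.6 to 278.5, 141.7 to 146.4 and 32.6 to 44.3 CPM in that order, so the libraries of the 3 genotypes did not overlap. The log2 fold change (± SE) was -2.85 ± 0.10 for homozygous against wild type (edgeR adjusted p = 5.59e-09), -0.89 ± 0.09 for heterozygous against wild type (6.96e-05) and -1.97 ± 0.10 for homozygous against heterozygous (1.16e-07). A second ID with the symbol NPC2 (ENSDARG00000096979) was at 1.96 ± 0.282, 1.41 ± 0.572 and 1.21 ± 0.136 CPM in wild-type, heterozygous and homozygous embryos. Its change in homozygous against wild-type embryos was -0.69 ± 0.25 (adjusted p = 0.0337), a call lost without homozygous replicate 1 or 2 or wild-type replicate 1 or 3 (adjusted p = 0.0571 to 0.118). The labels do not say which ID carries the mutation. NPC1, the membrane protein that receives cholesterol from NPC2 in the lysosome, was at 198 ± 4.2, 226 ± 8.74 and 277 ± 7.65 CPM in wild-type, heterozygous and homozygous embryos and rose in each comparison, by 0.49 ± 0.04, 0.20 ± 0.04 and 0.29 ± 0.04 (homozygous and heterozygous against wild type, and homozygous against heterozygous).

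In homozygous embryos, genes of cholesterol synthesis rose against wild type, with the highest median of the 33 lists tested. HMGCS1, which makes the precursor of mevalonate, went from 34.6 ± 2.01 to 802 ± 47.1 CPM, a 23.2-fold rise (log2 4.54 ± 0.06, adjusted p = 1.03e-18). Among the later enzymes of the pathway, SQLE (ENSDARG00000079946) rose by 4.29 ± 0.06, SC5D by 4.33 ± 0.07, MSMO1 by 5.55 ± 0.12, LSS by 4.45 ± 0.10 and FDPS by 2.90 ± 0.05 on the log2 scale. Cholesterol synthesis genes were higher, with a median log2 change of 3.83 (camera adjusted p = 8.29e-23, adjusted p = 0.0218 with an estimated correlation). Of 27 measured, 25 rose, 1 fell and 1 did not pass (25 up and 1 down adjusted over the list alone). ABCA1, a cholesterol exporter, fell (log2 -3.14 ± 0.10), and SOAT2, an enzyme that esterifies cholesterol, fell from 21.4 ± 0.575 to 0.362 ± 0.385 CPM. Cholesterol transport genes were not called as a list (camera adjusted p = 0.983). Of 20 measured, 6 rose, 5 fell and 9 did not pass (6 up and 5 down adjusted over the list alone).

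Lysosomal genes also rose in homozygous embryos. The membrane protein gene scarb2a went from 216 ± 4.11 to 1073 ± 90.6 CPM (log2 2.31 ± 0.06), and the protease gene ctsla from 838 ± 43.3 to 2166 ± 21.0 CPM (log2 1.37 ± 0.04). TFE3, a transcription factor of lysosomal genes, rose by 1.46 ± 0.08, and the peptidase gene TPP1 by 0.83 ± 0.05. Lysosome genes were higher, with a median log2 change of 0.29 (camera adjusted p = 1.19e-05, adjusted p = 0.0218 with an estimated correlation). Of 50 measured, 29 rose, 5 fell and 16 did not pass (31 up and 5 down adjusted over the list alone). A cathepsin B ID (CTSB) went the other way, from 460.2 ± 8.24 to 19.7 ± 16.7 CPM (log2 -4.60 ± 0.57, adjusted p = 8.24e-04). Autophagy genes were higher, with a median log2 change of 0.18 (camera adjusted p = 0.0162, adjusted p = 0.256 with an estimated correlation). Of 26 measured, 12 rose, 3 fell and 11 did not pass (13 up and 3 down adjusted over the list alone), and SQSTM1 and WIPI1 rose by 1.72 ± 0.07 and 0.71 ± 0.06. Genes of the lysosomal proton pump (V-ATPase) were higher, with a median log2 change of 0.27 (camera adjusted p = 0.00117, adjusted p = 0.131 with an estimated correlation). Of 21 measured, 13 rose, 1 fell and 7 did not pass (13 up and 1 down adjusted over the list alone), and ATP6V0C (ENSDARG00000036577) rose by 0.66 ± 0.06.

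Targets of Notch signalling fell in homozygous embryos. HEY1 went from 54.9 ± 2.26 to 14.6 ± 0.783 CPM (log2 -1.91 ± 0.08, adjusted p = 4.52e-12), and her12 from 90.7 ± 8.51 to 12.9 ± 0.903 CPM (log2 -2.82 ± 0.20). NRARP (ENSDARG00000018958) changed by -1.36 ± 0.06, HEY2 by -1.52 ± 0.10 and her8a by -1.82 ± 0.09. Notch targets were lower, with a median log2 change of -1.99 (camera adjusted p = 1.06e-09, adjusted p = 0.131 with an estimated correlation). Of 14 measured, 0 rose, 13 fell and 1 did not pass (0 up and 13 down adjusted over the list alone). The 14 included 5 her4 and 2 her15 copies, which are near-identical, so single copies are uncertain. Copies that share reads are not independent, so the count, median and p of the list rest partly on these families. The summed her4 level was 129.3 ± 29.5 CPM in wild type and 27.7 ± 4.77 in homozygous embryos. For her15 the summed level was 99.7 ± 15.8 and 22.5 ± 1.74 CPM. Among the pathway's own components the receptor gene NOTCH3 fell from 1023 ± 143 to 506 ± 15.4 CPM (log2 -1.02 ± 0.09, adjusted p = 1.48e-05). The glycosyltransferase gene LFNG (-0.52 ± 0.05) and the transcription factor gene RBPJ (ENSDARG00000003398, -0.44 ± 0.06) also fell. The ligand gene dlb rose by 0.86 ± 0.04. Notch components were not called as a list (camera adjusted p = 0.609). Of 31 measured, 10 rose, 10 fell and 11 did not pass (10 up and 10 down adjusted over the list alone).

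Neural progenitor markers were lower and neuron markers higher in homozygous embryos. SOX3, a progenitor gene, went from 388 ± 10.5 to 144 ± 11.8 CPM (log2 -1.43 ± 0.06), and sox19b and the glial filament gene GFAP changed by -1.23 ± 0.06 and -1.09 ± 0.05. Progenitor and glia markers were lower, with a median log2 change of -0.53 (camera adjusted p = 2.56e-05, adjusted p = 0.131 with an estimated correlation). Of 30 measured, 5 rose, 20 fell and 5 did not pass (6 up and 20 down adjusted over the list alone). The neurofilament gene nefma rose by 1.21 ± 0.05, INSM1 (ENSDARG00000091756) by 0.86 ± 0.05 and INA (ENSDARG00000053248) by 0.86 ± 0.06. Neuron markers were higher, with a median log2 change of 0.26 (camera adjusted p = 0.00465, adjusted p = 0.448 with an estimated correlation). Of 51 measured, 26 rose, 6 fell and 19 did not pass (26 up and 6 down adjusted over the list alone). Brain patterning genes were lower, with a median log2 change of -0.25 (camera adjusted p = 1.34e-04, adjusted p = 0.0790 with an estimated correlation). Of 44 measured, 7 rose, 24 fell and 13 did not pass (7 up and 25 down adjusted over the list alone), with ZIC1 at -1.17 ± 0.06 and NKX2-2 at -1.13 ± 0.07. Cell cycle genes were lower, with a median log2 change of -0.18 (camera adjusted p = 3.04e-06, adjusted p = 0.207 with an estimated correlation). Of 47 measured, 1 rose, 30 fell and 16 did not pass (1 up and 30 down adjusted over the list alone), with CCNE2 at -0.70 ± 0.05 and MCM5 at -0.49 ± 0.05.

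Inflammation genes were higher in homozygous embryos. SOCS3 (ENSDARG00000026611), an inhibitor of cytokine signalling, rose by 2.69 ± 0.08 and the transcription factor gene STAT3 by 1.55 ± 0.05. A rise from 5.62 ± 1.06 to 157 ± 17.9 CPM was measured for irg1l (log2 4.78 ± 0.13), and JUN rose by 0.81 ± 0.04. Inflammation and interferon genes were higher, with a median log2 change of 1.81 (camera adjusted p = 1.58e-10, adjusted p = 0.131 with an estimated correlation). Of 32 measured, 28 rose, 0 fell and 4 did not pass (28 up and 0 down adjusted over the list alone). Myeloid cell markers were higher, with a median log2 change of 0.35 (camera adjusted p = 0.0475, adjusted p = 0.174 with an estimated correlation). Of 28 measured, 11 rose, 2 fell and 15 did not pass (11 up and 2 down adjusted over the list alone), with CEBPB at 0.95 ± 0.06 and the leukocyte gene ptprc at 0.80 ± 0.13. The myeloid list shares il1b with the inflammation list and CEBPB with the list of unfolded protein and amino acid stress genes. Its rise is therefore not separate from theirs. The myeloid call was lost without heterozygous replicate 3, homozygous replicate 1 or 2, or wild-type replicate 1 or 3 (camera adjusted p = 0.0503 to 0.0690).

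Several tissue marker lists were lower in homozygous than in wild-type embryos. Skeletal muscle genes were lower, with a median log2 change of -0.32 (camera adjusted p = 3.04e-06, adjusted p = 0.131 with an estimated correlation). Of 43 measured, 3 rose, 26 fell and 14 did not pass (3 up and 26 down adjusted over the list alone). The list held both ACTA1 IDs, whose summed level was 4998 ± 198 CPM in wild type and 2046 ± 31.6 in homozygous embryos. Notochord and cartilage genes were lower, with a median log2 change of -0.33 (camera adjusted p = 2.56e-05, adjusted p = 0.131 with an estimated correlation). Of 30 measured, 2 rose, 18 fell and 10 did not pass (2 up and 19 down adjusted over the list alone). The cartilage matrix gene acana was at -1.63 ± 0.10 and SOX9 (ENSDARG00000043923) at -0.91 ± 0.07. Erythroid genes were lower, with a median log2 change of -0.31 (camera adjusted p = 7.29e-04, adjusted p = 0.146 with an estimated correlation). Of 28 measured, 2 rose, 16 fell and 10 did not pass (2 up and 17 down adjusted over the list alone), with the carbonic anhydrase gene cahz at -0.76 ± 0.06 and the globin gene hbae3 at -0.43 ± 0.04. Otic vesicle genes were lower, with a median log2 change of -0.23 (camera adjusted p = 0.00394, adjusted p = 0.0790 with an estimated correlation). Of 39 measured, 6 rose, 19 fell and 14 did not pass (7 up and 22 down adjusted over the list alone), with vcanb at -0.87 ± 0.05 and the inner ear matrix gene TECTA at -1.21 ± 0.10. Mural and neural crest mesenchyme genes were lower, with a median log2 change of -0.22 (camera adjusted p = 0.00465, adjusted p = 0.131 with an estimated correlation). Of 24 measured, 3 rose, 12 fell and 9 did not pass (3 up and 12 down adjusted over the list alone). Lens genes were lower, with a median log2 change of -0.21 (camera adjusted p = 0.00707, adjusted p = 0.526 with an estimated correlation). Of 29 measured, 1 rose, 10 fell and 18 did not pass (1 up and 10 down adjusted over the list alone). Tailbud and segmentation genes were lower, with a median log2 change of -0.22 (camera adjusted p = 0.0213, adjusted p = 0.131 with an estimated correlation). Of 26 measured, 5 rose, 12 fell and 9 did not pass (5 up and 13 down adjusted over the list alone). The tailbud call was lost without wild-type replicate 3 (camera adjusted p = 0.0516).

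In all, 9076 of 20375 genes differed between homozygous and wild-type embryos at an edgeR adjusted p under 0.05, 4783 higher and 4293 lower. Most changes were small: 984 genes were at least 2-fold higher and 575 at least 2-fold lower. The 3 libraries of both genotypes did not overlap for 53.9% of genes, where chance gives 10%. The largest rises by the naming rule also included arf4b (0.487 ± 0.0405 to 77.8 ± 13.6 CPM, log2 7.32 ± 0.20), cbx7a (4.83 ± 0.40) and CYB5R2 (4.75 ± 0.11). The largest falls also included gvin1l2, from 16.4 ± 3.78 CPM to 0.0850 ± 0.0346, near the level of 3 counts, as well as EGLN3 (-4.72 ± 0.21), EGLN2 (-3.49 ± 0.26), P4HA1 (-3.22 ± 0.40) and mt-atp8 (-2.89 ± 0.89, adjusted p = 0.0402). The call of mt-atp8 was lost without any one library except heterozygous replicate 3 (adjusted p = 0.0545 to 0.111) and with limma-voom (0.141). With an estimated correlation, the cholesterol synthesis and lysosome lists were the 2 of 18 called lists that passed.

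**Figure D2:**
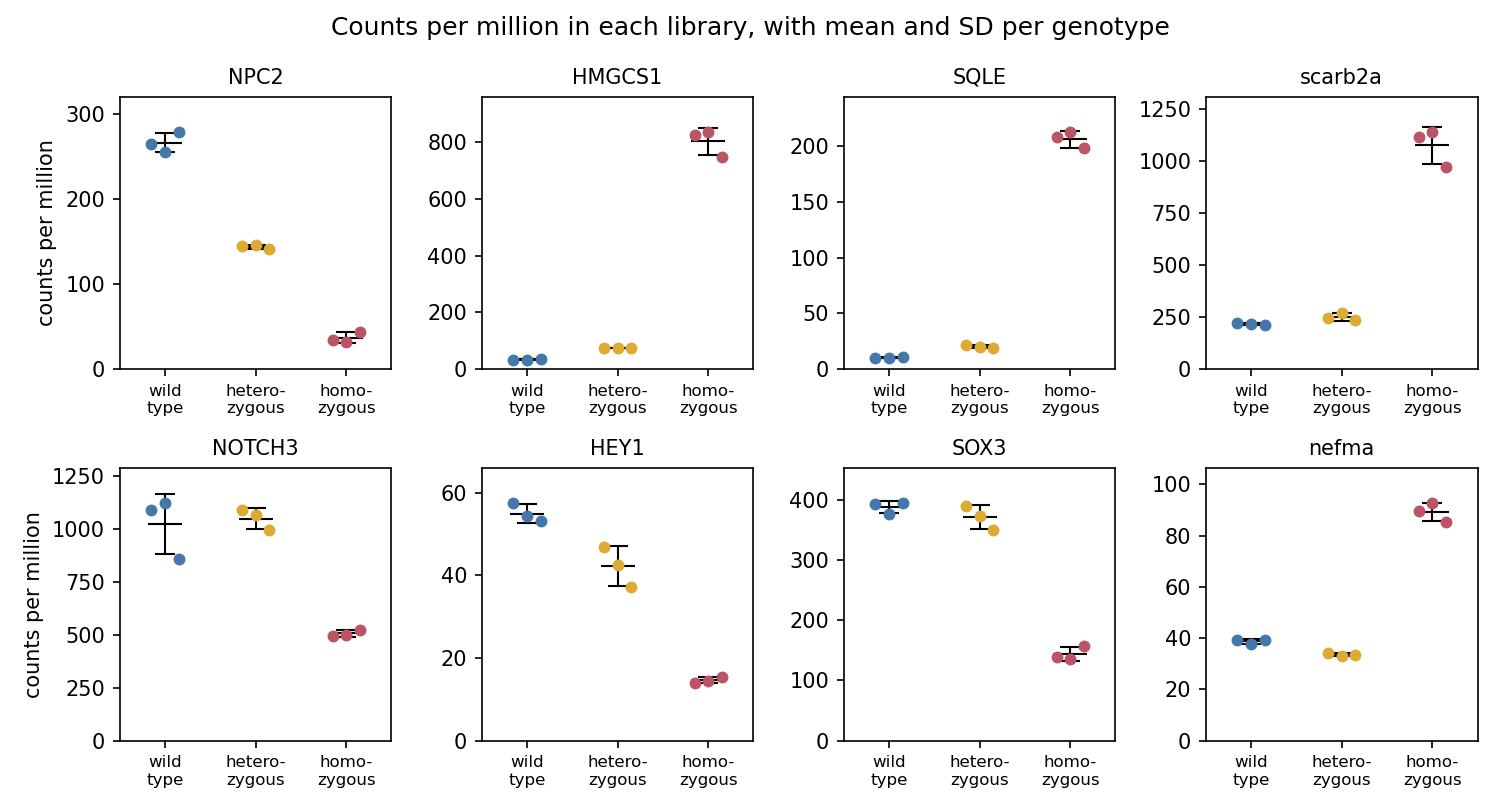
CPM (y axis, from 0) of NPC2 (ENSDARG00000090912), HMGCS1, SQLE (ENSDARG00000079946), scarb2a, NOTCH3, HEY1, SOX3 and nefma in each of the 3 libraries per genotype (points), with mean and SD (lines). NPC2 was lowest in homozygous libraries, HMGCS1, SQLE, scarb2a and nefma were highest there, and NOTCH3, HEY1 and SOX3 were lowest there.

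In heterozygous embryos, cholesterol synthesis genes were also above wild type. HMGCS1 was at 74.8 ± 1.43 CPM, 2.16-fold above wild type (log2 1.11 ± 0.05, adjusted p = 3.69e-10), and SQLE (ENSDARG00000079946), SC5D and MVD rose by 0.94 ± 0.06, 0.95 ± 0.07 and 0.76 ± 0.07. Cholesterol synthesis genes were higher, with a median log2 change of 0.56 (camera adjusted p = 1.21e-10, adjusted p = 0.0891 with an estimated correlation). Of 27 measured, 21 rose, 0 fell and 6 did not pass (23 up and 1 down adjusted over the list alone). Notch targets were not called as a list (camera adjusted p = 0.398). Of 14 measured, 0 rose, 2 fell and 12 did not pass (0 up and 1 down adjusted over the list alone). HEY1 was at -0.38 ± 0.07 (adjusted p = 8.68e-04) and NOTCH3 at 0.04 ± 0.09 (adjusted p = 0.805). For her8a the change was -0.26 ± 0.09 (adjusted p = 0.0347), a call lost without any one heterozygous or wild-type library (adjusted p = 0.0754 to 0.110). Lysosome genes were not called as a list (camera adjusted p = 0.398). Of 50 measured, 14 rose, 5 fell and 31 did not pass (15 up and 5 down adjusted over the list alone), with ctsla up by 0.46 ± 0.04, LAMP2 by 0.46 ± 0.05 and PSAP by 0.35 ± 0.04.

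Among the largest rises in heterozygous embryos by the naming rule, the photolyase gene cry5 went from 3.34 ± 0.214 to 19.7 ± 0.773 CPM (log2 2.57 ± 0.09, adjusted p = 7.94e-12). cry-dash rose by 1.68 ± 0.06, and the clock genes PER2 and CRY1 (ENSDARG00000045768) by 1.53 ± 0.07 and 1.52 ± 0.05. Among the largest falls, the prolyl hydroxylase gene EGLN3 went from 35.6 ± 8.57 to 1.44 ± 0.186 CPM (log2 -4.62 ± 0.21), and EGLN2, P4HA1, P4HA2 and HIF1AN were at -4.17 ± 0.28, -3.13 ± 0.40, -1.75 ± 0.08 and -1.87 ± 0.08. Glycolysis and hypoxia genes were lower, with a median log2 change of -0.24 (camera adjusted p = 3.32e-06, adjusted p = 0.0891 with an estimated correlation). Of 47 measured, 3 rose, 24 fell and 20 did not pass (4 up and 26 down adjusted over the list alone), with LDHA at -0.57 ± 0.05 and PFKFB3 at -1.38 ± 0.11. The glucose-responsive gene TXNIP (ENSDARG00000070000) was at -2.12 ± 0.10 and G6PC1 (ENSDARG00000013721), the last enzyme of glucose release, at -2.44 ± 0.14.

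Stress, inflammation and tissue marker lists were lower in heterozygous than in wild-type embryos. Unfolded protein and amino acid stress genes were lower, with a median log2 change of -0.25 (camera adjusted p = 3.32e-06, adjusted p = 0.145 with an estimated correlation). Of 40 measured, 2 rose, 20 fell and 18 did not pass (4 up and 25 down adjusted over the list alone), with ppp1r15a at -1.67 ± 0.08 and DDIT4 at -1.31 ± 0.08. Inflammation and interferon genes were lower, with a median log2 change of -0.60 (camera adjusted p = 0.00123, adjusted p = 0.515 with an estimated correlation). Of 32 measured, 1 rose, 11 fell and 20 did not pass (1 up and 11 down adjusted over the list alone), with JUN at -0.37 ± 0.04. Neuron markers were lower, with a median log2 change of -0.19 (camera adjusted p = 3.47e-05, adjusted p = 0.395 with an estimated correlation). Of 51 measured, 2 rose, 25 fell and 24 did not pass (2 up and 28 down adjusted over the list alone). The proneural gene neurog1 went from 71.1 ± 2.30 to 33.1 ± 1.93 CPM (log2 -1.1 ± 0.06), and ascl1b and ascl1a changed by -0.62 ± 0.05 and -0.58 ± 0.06. Brain patterning genes were lower, with a median log2 change of -0.18 (camera adjusted p = 1.21e-04, adjusted p = 0.0891 with an estimated correlation). Of 44 measured, 0 rose, 18 fell and 26 did not pass (0 up and 21 down adjusted over the list alone). Skeletal muscle genes were lower, with a median log2 change of -0.17 (camera adjusted p = 3.30e-04, adjusted p = 0.382 with an estimated correlation). Of 43 measured, 3 rose, 21 fell and 19 did not pass (3 up and 21 down adjusted over the list alone). Notochord and cartilage genes were lower, with a median log2 change of -0.21 (camera adjusted p = 0.00100, adjusted p = 0.373 with an estimated correlation). Of 30 measured, 2 rose, 13 fell and 15 did not pass (2 up and 14 down adjusted over the list alone). Erythroid genes were lower, with a median log2 change of -0.19 (camera adjusted p = 0.00291, adjusted p = 0.373 with an estimated correlation). Of 28 measured, 1 rose, 13 fell and 14 did not pass (2 up and 13 down adjusted over the list alone). Mural and neural crest mesenchyme genes were lower, with a median log2 change of -0.17 (camera adjusted p = 0.00123, adjusted p = 0.145 with an estimated correlation). Of 24 measured, 1 rose, 8 fell and 15 did not pass (1 up and 10 down adjusted over the list alone). Retina genes were lower, with a median log2 change of -0.16 (camera adjusted p = 0.0157, adjusted p = 0.395 with an estimated correlation). Of 28 measured, 0 rose, 9 fell and 19 did not pass (0 up and 10 down adjusted over the list alone). Progenitor and glia markers were lower, with a median log2 change of -0.20 (camera adjusted p = 0.0347, adjusted p = 0.481 with an estimated correlation). Of 30 measured, 4 rose, 12 fell and 14 did not pass (6 up and 13 down adjusted over the list alone). The progenitor call was lost without heterozygous replicate 3 or wild-type replicate 1 (camera adjusted p = 0.0989 and 0.0823) and with a filter of 1 CPM in 3 libraries (0.0607). The retina call was lost without heterozygous replicate 3 or wild-type replicate 2 (camera adjusted p = 0.0750 and 0.0524).

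Heterozygous and wild-type embryos differed in 6079 of 20375 genes, 3154 higher and 2925 lower, of which 285 and 309 by at least 2-fold. The libraries of both genotypes did not overlap for 42.7% of genes, where chance gives 10%. Other large rises were CTCF (4.72 ± 0.47), NENF (1.70 ± 0.35), krt18b (1.26 ± 0.14), lonrf1 (1.36 ± 0.07), SLC16A12 (ENSDARG00000089885, 1.41 ± 0.10) and GABPA (1.25 ± 0.36, adjusted p = 0.0405). Other large falls were gvin1l2 (-4.11 ± 0.55), map1lc3cl (-1.77 ± 0.11) and hmmr (-3.19 ± 0.78, adjusted p = 0.0245). The GABPA call was lost without homozygous replicate 2 or 3 or any wild-type library (adjusted p = 0.0642 to 0.114). It was also lost with limma-voom (0.0803), with no low-count filter (0.0559) and in a fit of only the 2 genotypes (0.0840). The hmmr call was lost without heterozygous replicate 1 or 2 or any wild-type library (adjusted p = 0.0520 to 0.0822). With an estimated correlation none of the 12 called lists passed, the lowest adjusted p being 0.0891.

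Homozygous and heterozygous embryos shared parents and maternal genotype. HMGCS1 was 10.7-fold higher in homozygous embryos (log2 3.42 ± 0.06, adjusted p = 4.24e-17), and SQLE (ENSDARG00000079946), SC5D and FDPS rose by 3.35 ± 0.06, 3.38 ± 0.06 and 2.43 ± 0.05. Cholesterol synthesis genes were higher, with a median log2 change of 3.04 (camera adjusted p = 3.09e-23, adjusted p = 0.0128 with an estimated correlation). Of 27 measured, 25 rose, 1 fell and 1 did not pass (25 up and 1 down adjusted over the list alone). SOAT2 and ABCA1 fell, with log2 changes of -5.56 ± 0.46 and -3.48 ± 0.10, and the lipase gene ABHD6 (ENSDARG00000060756) was at -2.74 ± 0.13. Lysosome genes were higher, with a median log2 change of 0.28 (camera adjusted p = 8.74e-07, adjusted p = 0.0128 with an estimated correlation). Of 50 measured, 29 rose, 1 fell and 20 did not pass (32 up and 1 down adjusted over the list alone), with scarb2a at 2.1 ± 0.06 and ctsla at 0.91 ± 0.04. Autophagy genes were higher, with a median log2 change of 0.32 (camera adjusted p = 3.01e-05, adjusted p = 0.168 with an estimated correlation). Of 26 measured, 17 rose, 1 fell and 8 did not pass (18 up and 1 down adjusted over the list alone), with WIPI1 at 0.94 ± 0.06. V-ATPase genes were higher, with a median log2 change of 0.21 (camera adjusted p = 0.00800, adjusted p = 0.201 with an estimated correlation). Of 21 measured, 10 rose, 1 fell and 10 did not pass (10 up and 1 down adjusted over the list alone), with atp6ap1a at 0.72 ± 0.08.

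Notch targets fell in homozygous against heterozygous embryos. NRARP (ENSDARG00000018958) was at -1.28 ± 0.06, HEY1 at -1.54 ± 0.08, her8a at -1.56 ± 0.09 and her12 at -2.69 ± 0.20. Notch targets were lower, with a median log2 change of -1.99 (camera adjusted p = 4.07e-10, adjusted p = 0.168 with an estimated correlation). Of 14 measured, 0 rose, 13 fell and 1 did not pass (0 up and 13 down adjusted over the list alone). The 14 again included the 5 her4 and 2 her15 copies. NOTCH3 fell from 1049 ± 49.1 to 506 ± 15.4 CPM (log2 -1.05 ± 0.09, adjusted p = 1.43e-05), while the ligand genes dlb and dll4 rose by 0.96 ± 0.04 and 0.58 ± 0.07. Notch components were not called as a list (camera adjusted p = 0.589). Of 31 measured, 11 rose, 7 fell and 13 did not pass (11 up and 9 down adjusted over the list alone). Neuron markers were higher, with a median log2 change of 0.42 (camera adjusted p = 5.09e-10, adjusted p = 0.168 with an estimated correlation). Of 51 measured, 34 rose, 2 fell and 15 did not pass (37 up and 2 down adjusted over the list alone), with nefma at 1.41 ± 0.05 and INA (ENSDARG00000053248) at 1.1 ± 0.06. Progenitor and glia markers were lower, with a median log2 change of -0.36 (camera adjusted p = 4.97e-04, adjusted p = 0.168 with an estimated correlation). Of 30 measured, 8 rose, 19 fell and 3 did not pass (8 up and 19 down adjusted over the list alone), with SOX3 at -1.36 ± 0.06 and the glutamate transporter gene SLC1A3 (ENSDARG00000104431) at -0.88 ± 0.05. Cell cycle genes were lower, with a median log2 change of -0.24 (camera adjusted p = 3.0e-09, adjusted p = 0.168 with an estimated correlation). Of 47 measured, 0 rose, 33 fell and 14 did not pass (0 up and 36 down adjusted over the list alone), with MCM5 at -0.50 ± 0.05.

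Inflammation genes rose in homozygous against heterozygous embryos. SOCS3 (ENSDARG00000026611) was at 2.86 ± 0.08, STAT3 at 1.63 ± 0.05, and the matrix protease gene MMP9 went from 6.66 ± 1.70 to 249.8 ± 42.5 CPM (log2 5.24 ± 0.56). Inflammation and interferon genes were higher, with a median log2 change of 2.24 (camera adjusted p = 2.18e-15, adjusted p = 0.168 with an estimated correlation). Of 32 measured, 29 rose, 0 fell and 3 did not pass (30 up and 0 down adjusted over the list alone). Unfolded protein and amino acid stress genes were higher, with a median log2 change of 0.32 (camera adjusted p = 2.12e-05, adjusted p = 0.168 with an estimated correlation). Of 40 measured, 23 rose, 5 fell and 12 did not pass (23 up and 5 down adjusted over the list alone), with DDIT3 at 1.91 ± 0.07 and SLC7A3 (ENSDARG00000020645) at 1.27 ± 0.07. Glycolysis and hypoxia genes were higher, with a median log2 change of 0.18 (camera adjusted p = 0.0302, adjusted p = 0.201 with an estimated correlation). Of 47 measured, 22 rose, 7 fell and 18 did not pass (22 up and 8 down adjusted over the list alone), with IGFBP1 at 2.44 ± 0.12 and PFKFB4 at 1.27 ± 0.05. Neither the stress nor the glycolysis list was called in homozygous against wild-type embryos. There the stress list had a median of 0.23 (camera adjusted p = 0.252, 20 up and 12 down). The glycolysis list had a median of -0.11 (camera adjusted p = 0.168, 13 up and 18 down). Myeloid cell markers were higher, with a median log2 change of 0.24 (camera adjusted p = 0.0312, adjusted p = 0.168 with an estimated correlation). Of 28 measured, 10 rose, 0 fell and 18 did not pass (10 up and 0 down adjusted over the list alone). Here too the myeloid call rested on heterozygous replicate 3 (camera adjusted p = 0.0660 without it).

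Tissue markers also differed between the sibling genotypes. Skeletal muscle genes were lower, with a median log2 change of -0.15 (camera adjusted p = 5.16e-04, adjusted p = 0.211 with an estimated correlation). Of 43 measured, 3 rose, 21 fell and 19 did not pass (3 up and 21 down adjusted over the list alone). Fibroblast and matrix genes were lower, with a median log2 change of -0.17 (camera adjusted p = 0.0302, adjusted p = 0.168 with an estimated correlation). Of 42 measured, 9 rose, 21 fell and 12 did not pass (11 up and 22 down adjusted over the list alone), with the fin fold gene and3 at -1.43 ± 0.05. The fibroblast call was lost with a filter of 1 CPM in 3 libraries (camera adjusted p = 0.0515). Notochord and cartilage genes were lower, with a median log2 change of -0.12 (camera adjusted p = 0.0435, adjusted p = 0.380 with an estimated correlation). Of 30 measured, 3 rose, 11 fell and 16 did not pass (3 up and 11 down adjusted over the list alone). The notochord call was lost without heterozygous replicate 1 or 2 or homozygous replicate 1 or 3 (camera adjusted p = 0.0505 to 0.0680). It was also lost with the filter of 1 CPM (0.0826) and with halved counts, chosen after seeing the data (0.0550). Otic vesicle genes were not called as a list (camera adjusted p = 0.0746). Of 39 measured, 8 rose, 17 fell and 14 did not pass (8 up and 17 down adjusted over the list alone), with vcanb at -0.87 ± 0.05. Erythroid genes were not called as a list (camera adjusted p = 0.128). Of 28 measured, 4 rose, 10 fell and 14 did not pass (5 up and 11 down adjusted over the list alone), with cahz at -0.46 ± 0.06.

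Homozygous and heterozygous embryos differed in 8101 of 20375 genes, 4155 higher and 3946 lower, of which 716 and 240 by at least 2-fold. The libraries did not overlap for 51.2% of genes, where chance gives 10%. Large rises also included arf4b (7.03 ± 0.19), irg1l (5.55 ± 0.13), tcap (4.43 ± 0.19), bcl3 (4.32 ± 0.43) and CYP24A1 (4.23 ± 0.27). Large falls also included CTSB (-3.74 ± 0.55), atp1a1a.3 (-2.74 ± 0.26) and gvin1l2 (adjusted p = 0.0339), whose call was lost without any homozygous library or wild-type replicate 2 (adjusted p = 0.0511 to 0.104) and with limma-voom (0.116). The cholesterol synthesis and lysosome lists were the 2 of 15 called lists that passed with an estimated correlation.

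**Figure D3:**
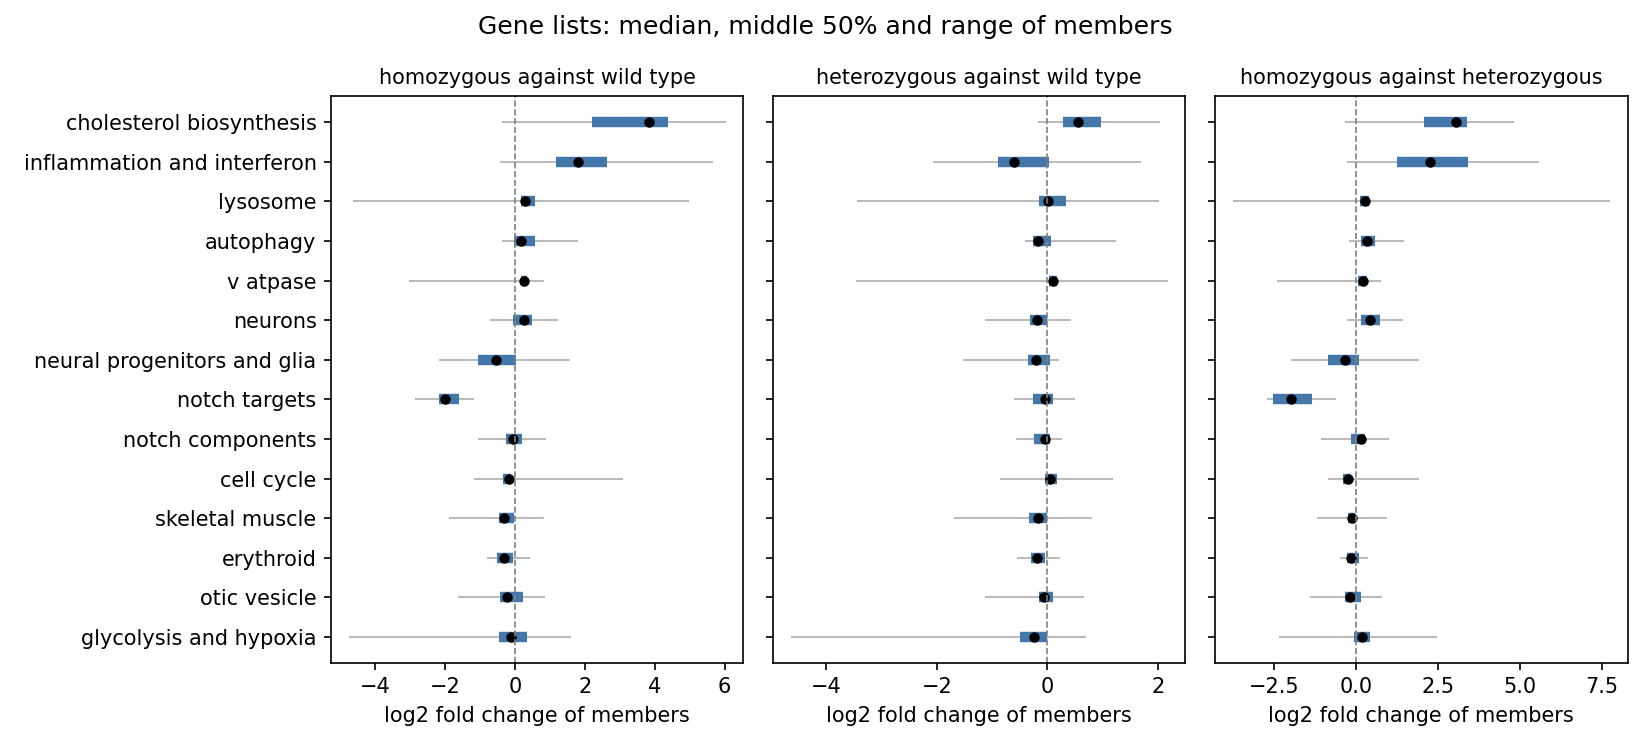
Log2 fold changes (x axis, a separate scale per panel) of the measured members of 14 gene lists in the 3 comparisons. Points are medians, thick bars span the middle 50% of members and thin lines their range. Cholesterol synthesis genes lie highest in homozygous embryos (medians of 3.83 and 3.04), and Notch targets lie lowest there (median of -1.99 in both comparisons).

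The homozygous libraries enter both comparisons with the other genotypes. Of the genes called against wild type and against heterozygous siblings, 2904 were higher and 2343 lower in both, and 309 were called in opposite directions. Independent lists of these sizes would share 975.4 and 831.4. Unchanged groups simulated with shared libraries gave a mean of 0.150 shared calls over 20 simulations. No gene was changed there, so few calls were possible, and such counts are no reference for the overlaps here or below. The covariance of log2 fold changes was 0.293, beside 0.0405 in the simulations, and the correlation across genes was 0.658 beside 0.491. Heterozygous and homozygous embryos against the shared wild type had 1648 genes higher and 1731 lower in both (740.4 and 616.3 for independent lists, mean of 0.200 in simulations) and 530 in opposite directions. Here the covariance was 0.247 beside 0.0429, and the correlation 0.593 beside 0.513. With 3 libraries per genotype the shared libraries are too few to split, so part of each excess may come from sharing them.

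Besides Notch components and cholesterol transport, 9 lists were not called in any comparison. In homozygous against wild-type embryos the camera adjusted p was, in parentheses, for endothelial (0.221), p53 response (0.422), heat shock (0.609), pigment cells (0.520) and cardiac genes (0.971). Epidermis and ionocytes (0.422), hatching gland (0.978), yolk syncytial layer and liver (0.975) and motile cilia and axis straightening (0.391) did not pass either. The median, mean and test of uncalled lists differed in sign for cardiac, hatching gland and yolk syncytial layer and liver genes in this comparison. They also did so for cholesterol transport, lysosome, heat shock, motile cilia, myeloid and epidermis genes in heterozygous against wild-type embryos and for heat shock genes in homozygous against heterozygous embryos. Among the 9 lists, p53 response genes came closest to a call, in homozygous against heterozygous embryos (camera adjusted p = 0.0521, 12 up and 3 down of 30). Hatching gland genes followed in heterozygous against wild-type embryos (camera adjusted p = 0.0909, 0 up and 3 down of 11).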

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

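The tests of the Notch target fall were all chosen after the result was seen, while the tests of the 2 lists below were fixed beforehand. Inflammation genes and neuron markers were called in opposite directions in the mutant genotypes, down in heterozygous and up in homozygous embryos against wild type. With an estimated correlation all 4 of these calls were lost, with an adjusted p of 0.515 and 0.131 for inflammation genes and 0.395 and 0.448 for neuron markers (heterozygous and homozygous). The difference itself, tested as homozygous against heterozygous, had a camera adjusted p of 2.18e-15 for inflammation genes (29 up and 0 down of 32) and of 5.09e-10 for neuron markers (34 up and 2 down of 51). This too was lost with an estimated correlation (adjusted p = 0.168 for both).

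Notch targets fell in homozygous against heterozygous embryos with a median log2 change of -1.99 over 14 genes, of which 5 were her4 and 2 were her15 copies. A younger age of homozygous embryos at collection would lower neuron markers relative to tailbud and segmentation genes. The difference of their medians was 0.628 (95% bootstrap interval over genes 0.220 to 0.820, 48 and 25 genes), the direction of an older age. An older age would raise skeletal muscle and lens genes, but their median was -0.143 (-0.184 to -0.0920, 72 genes), the direction of a younger age. This rests mainly on muscle, with medians of -0.147 for 43 muscle and -0.0873 for 29 lens genes. The lens list was not called here (camera adjusted p = 0.0770, 0 up and 3 down). A shift of age alone would not give both the neuron and the muscle result. These lists may themselves change with genotype or with Notch signalling, so they cannot decide whether age had a part in the fall. Fewer progenitor cells could account for part of the fall. The targets lay below progenitor and glia markers by a difference of medians of -1.63 (-2.28 to -0.896, 14 and 30 genes). A loss of the size of the markers' median alone would not give the fall. That list was mixed, with 8 genes higher and 19 lower, and SOX3 fell about as far as the target NRARP (ENSDARG00000018958). A larger loss of some progenitors is therefore not excluded. Reads shared among the 5 her4 copies are argued against by their summed level, with a log2 ratio of -2.50. Genes of a list move together, and the her4 and her15 copies may share reads, so these intervals are too narrow. Lower Notch signalling, sorting by phenotype and other changes of cell types remain open and untested, and parts played by age or progenitor loss are not decided.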

How the results depend on the processing

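The halved counts were chosen after seeing the data. Apart from the number of called lists, each count of called genes, the overlaps and the NPC2 changes stayed within 1.5 times of, and on the same side as, the reported values under every alternative run for them. Without one library, called genes numbered 7783 to 9263 (homozygous against wild type, 4066 to 4787 higher and 3714 to 4476 lower), 4835 to 6277 (heterozygous against wild type, 2473 to 3090 and 2362 to 3187) and 6776 to 8482 (homozygous against heterozygous, 3544 to 4322 and 3192 to 4160). The log2 change of NPC2 (ENSDARG00000090912) was -3.0 to -2.78, -0.91 to -0.85 and -2.1 to -1.88, called lists 16 to 18, 11 to 14 and 14 to 16, and same-direction overlaps 4294 to 5058 and 2747 to 3212. Under the other alternatives called genes numbered 8644 to 9162, 5769 to 6165 and 7966 to 8363. Camera with an estimated correlation called 2, 0 and 2 lists, and fry, which does not compare a list with other genes, called 26, 19 and 27. The cause was not tested. With the replicate block, 9073, 6133 and 8164 genes were called. Libraries with the same number had deviations correlated at -0.0242 to 0.0848. Between heterozygous and homozygous libraries, same-number pairs were at 0.0565 to 0.0848 and other pairs at -0.0764 to 0.0267. These correlations were low, but a weak pairing of the siblings by number stays open. The block ended the calls of mt-atp8 (adjusted p = 0.0682) and the myeloid list (camera adjusted p = 0.0540) in homozygous and of her8a (0.0557) in heterozygous against wild-type embryos. Without one library, 3 uncalled changes reached the other sign: NOTCH3 in heterozygous against wild-type embryos (-0.075 to 0.11, reported 0.04) and, in homozygous against heterozygous embryos, NPC2 ENSDARG00000096979 (-0.48 to 0.12, reported -0.23) and EGLN3 (-0.25 to 0.017, reported -0.11), also with no test of the cause. Depth limits genes near 3 counts, such as gvin1l2 in homozygous embryos.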

Other observations

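All tests on light, clock and hydroxylase genes, and both of these lists, were chosen after the values were seen, as was the share of calls on other chromosomes, while the counts over splits and the odds ratio for linkage were planned before. Of 24 tested genes of light response and the circadian clock, 11 rose and 3 fell in heterozygous against wild-type embryos, and 11 rose and 1 fell in homozygous against wild-type embryos. Of these, 9 rose in both and 1 fell in both. No enrichment was tested for either list. The photolyase gene cry5 was at 3.34 ± 0.214 CPM in wild type, 19.7 ± 0.773 in heterozygous and 13.0 ± 0.529 in homozygous embryos, and PER2, a clock gene, at 26.8 ± 2.16, 77.3 ± 5.39 and 56.7 ± 0.972 CPM. Of 13 tested prolyl, asparaginyl and lysyl hydroxylase genes, 8 fell in both mutant genotypes and 0 rose. The oxygen sensor gene EGLN3 was at 35.6 ± 8.57, 1.44 ± 0.186 and 1.37 ± 0.280 CPM and HIF1AN at 83.1 ± 11, 22.8 ± 0.640 and 24.8 ± 0.539 CPM.

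Sibling embryos shared parents and mother but differed in the dose of the mutant allele, and a graded dose effect would carry these changes on from heterozygous to homozygous embryos. For the genes called the same way in both genotypes, the median ratio of the homozygous against heterozygous change to the heterozygous against wild-type change was -0.257 (10 light and clock genes, 95% bootstrap interval over genes -0.307 to 0.206) and 0.0463 (8 hydroxylase genes, -0.0676 to 0.221). Both intervals lie under the bound of 0.5, which argues against a graded dose effect as the whole cause for these called genes only. They were chosen after large heterozygous changes were seen, and the heterozygous libraries enter both changes of the ratio, which both favour a low ratio. Genes of a list also move together, so these intervals are too narrow. EGLN3 changed by -4.62 ± 0.21 in heterozygous against wild-type embryos and was at -0.11 ± 0.25 between the siblings, and cry5 rose by 2.57 ± 0.09 and then fell (log2 -0.60 ± 0.08), while dbpa went on rising, by 0.87 ± 0.19 and 0.69 ± 0.17. The change between the siblings was the smaller one for 10 of the 10 and 8 of the 8 genes. An effect already complete with 1 mutant copy, parents, maternal genotype, time of day and collection conditions may each account for the part shared by both mutant genotypes. They cannot be told apart because all wild-type embryos came from other crosses. Between the siblings, 4 of the 24 light and clock genes rose and 8 fell, and 1 of the 13 hydroxylase genes rose and 2 fell. Shared parents, a shared mother or a complete effect would not give these sibling differences.

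Variants linked to npc2 could differ between sibling genotypes. Of genes with a known chromosome, 211 of 548 on the chromosome of npc2 and 5859 of 13890 on others were called in homozygous against heterozygous embryos (odds ratio 0.859, 95% interval 0.717 to 1.03, two-sided Fisher's exact test p = 0.0936). The odds ratio is void, because 74.9% of called genes had a chromosome in the table used, under the minimum of 80%. At least 72.3% of the 8101 called genes lay on other chromosomes, counting genes without a known chromosome as on that of npc2, which argues against variants acting only on that chromosome's genes as the whole cause. Such variants for genes on it, and linked variants acting on genes elsewhere, stay open.

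Each pair of genotypes allows 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. In each of the 3 comparisons 1 split, the real one, gave the highest number of called genes. The real values were 9076, 6079 and 8101 (homozygous against wild type, heterozygous against wild type, homozygous against heterozygous), and the highest of the other splits were 1, 2 and 2. Every other split mixes both genotypes in each group, so the genotype differences enter the spread within groups. Low counts follow from this mixing, and they are no reference for the calls made by chance.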
